A study of Caenorhabditis elegans with 2 samples.

How the data were processed

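Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed with an affinity-purified rabbit polyclonal antibody against SCC-1 on extracts of adult Caenorhabditis elegans of the strain fem-2(b245), and a library of input DNA was made from the same kind of material. Per the labels' protocols, frozen worms were ground, fixed with 1% formaldehyde for 10 minutes and sonicated, 5 µg of antibody was used, and 10 ng of input DNA entered library preparation. The series design gives a temperature of 20 °C. The series has 2 samples, 1 of ChIP DNA and 1 of input DNA, and each was labelled as replicate 1.

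The 1 processed file used here was the peak list of the ChIP sample. Peaks were called with MACS on the WormBase WS220 build, per the file header and the source column. BWA and the ce10 build, which is the UCSC name of WS220, are listed in the submitters' processing notes. The versions of MACS and BWA, the calling threshold and whether the input library served as the control are not given in the sources used here. Each peak carries the first and last base and a score that the authors deposited, which is the peak's own value within this list. The file does not state the scale of the score. Scores ran from 50.0 to 3219 with 2 decimals, 437 peaks shared the value 3100 exactly, 14 peaks scored from 3000 up to 3100 and 20 scored above 3100. The value 3100 was therefore treated as a ceiling, peaks of 3100 or more were taken as 1 tied class, and their order was not interpreted. If 3100 stands for a p-value too small to compute, which the file does not say, the 437 tied peaks would rank above the 20 with a larger number. No read counts were used, so the sequencing depth behind each peak is unknown and no interval for a peak's own signal can be given.

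Positions are given in WS220, counted from 1. No chromosome lengths of this build were used, so the length of each chromosome was taken as the end of its last peak, which understates it slightly. The 6 nuclear chromosomes were analysed, with peaks placed by their midpoints. Arms were defined as the outer 2 of 4 equal parts of each chromosome. The gene table at hand belongs to another build, WBcel235, so no peak was assigned to a gene, exon, intron or gene start. It was used only to count protein-coding genes (19971 over the 6 chromosomes) and tRNA genes (612) per chromosome. The planned comparisons of gene starts within 500 bp, exons and introns, tRNA genes, gene lists, the scores at gene starts and the GC content of peaks were therefore not made.

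The main comparisons, their tests and the rule for naming peaks were fixed before the data were examined. The permutation test of width and all Fisher's exact tests between X and the autosomes were not among them. The peaks named are the 10 with the highest score and the 3 highest on each chromosome, with ties broken by width and then by chromosome and start. The widest peaks, the windows with most or fewest peaks, the longest stretches without a peak, the first peak of each chromosome and the top-class peaks in the first Mb of X were chosen for naming after their values were seen. Ratios of densities carry exact Clopper-Pearson 95% intervals from the share of peaks on X, and densities carry exact Poisson intervals. These cover counting error only. Medians of score and width were compared between X and autosomal peaks with two-sided permutation tests of 100000 draws, and shares with two-sided Fisher's exact tests. Peaks are not replicates and neighbouring peaks are not independent, so all such p-values describe this list and not the variation between animals. Distances between neighbouring peaks were compared with 1000 random placements without overlap of the same peaks on their own chromosomes, and the shares on arms with 10000 circular rotations, which keep the spacing of neighbouring peaks. The rotations, the division by score, the windows of 1 Mb (10000 bootstrap draws), the merging of peaks closer than 5000 bp, the comparison within 5 classes of width and the removal of chromosome ends were added after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

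The procedures were tested on simulated data. With a simulated X to autosome ratio of 0.25, 94 of 100 intervals held that value, and with a simulated arm share of 40%, 91 of 100 did. The peaks of these simulations were placed independently of each other. They therefore do not show how often the intervals hold the true value when peaks are clustered. All 20 simulated clustered lists had a shorter median distance than every random placement, against 0 of 20 lists placed at random. Alternatives were the higher-scoring 50% of the peaks, the merging of peaks closer than 200 bp, other definitions of arms and of density, and the omission of each autosome in turn.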

Results

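The binding of SCC-1 was mapped by ChIP-seq in fem-2(b245) adult hermaphrodites described as germline-containing young adults. SCC-1 is the kleisin subunit of mitotic cohesin, the ring complex that holds sister chromatids together, and fem-2 encodes a phosphatase of the sex determination pathway. The data comprised 1 ChIP library and 1 input DNA library, and the values below come from the peak list of the ChIP library. With 1 library there was no replicate error, and the comparisons were made between chromosomes and regions within that list. The number of reads behind the list is unknown.

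SCC-1 peaks were found on all 6 chromosomes. The list held 4534 peaks, which covered 8.84 Mb or 8.83% of the chromosomes. The median width was 1490 bp with quartiles of 1121 and 2246 bp, and 176 peaks (3.88%) were at least 5000 bp wide. The widest peak spanned 16404 bp on chromosome II from 11964487 to 11980890 and had a score of 2311. The next widest, also on II, ran from 14597954 to 14612413 over 14460 bp and had the tied score of 3100. A peak of 12326 bp on III, from 321364 to 333689, had a score of only 115.87. Width and score were related across peaks (Spearman's rho = 0.69), although peaks are not independent replicates.

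Peaks of the top score class were found on all 6 chromosomes. In total 457 peaks (10.1%) scored 3100 or more, and these cannot be ranked among themselves because 437 shared 1 value, which may be a ceiling that stands above the 20 larger numbers. The peaks with the largest listed numbers are given here by position, not as the strongest. The largest number, 3219, was listed for a peak on IV from 4657556 to 4661590. Chromosome IV also held peaks at 418575 to 428075 with a score of 3214 and at 4467474 to 4474059 with a score of 3197. On I, the peaks at 5157498 to 5163201 and 517853 to 520929 scored 3217 and 3216, and a further peak lay at 3786942 to 3790450 with 3172. On II, the peak at 11873961 to 11881666 scored 3198 and that at 12002556 to 12008040 scored 3173. On III, peaks at 13641789 to 13644270, 3067585 to 3070660 and 4751687 to 4755927 scored 3193, 3190 and 3159. On V, peaks at 1194812 to 1198186 and 7852769 to 7856597 scored 3191 and 3113. On X, a peak of 1211 bp from 11093510 to 11094720 was listed with 3182, and the other 30 top-class peaks of X with 3100. The remaining named peaks had the tied score of 3100 and were named for their width, namely the 14460 bp peak on II, 10018035 to 10028796 on V, and 16929008 to 16939824 and 2056684 to 2064281 on X.

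The X chromosome carried far fewer SCC-1 peaks than any autosome. X, which is the target of dosage compensation in hermaphrodites and is largely silent in much of the germline, held 252 peaks, or 5.56% of all peaks on 17.7% of the chromosome length. Its density was 14.2 peaks per Mb (95% interval 12.52 to 16.097), against 51.98 (50.4 to 53.6) over the 5 autosomes. The ratio of X to autosomes was 0.274 (95% interval 0.240 to 0.311). The autosomes themselves differed, from 36.8 peaks per Mb on V and 46.3 on IV to 50.5 on II, 66.8 on III and 67.6 on I. Peaks covered 2.11% of X and 10.3% of the autosomes, from 6.66% on V to 13.8% on III.

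The shortage on X was seen along its whole length. Windows of 1 Mb held 13.8 ± 5.11 peaks on X (SD, n = 17 windows) and 52.1 ± 18.6 on the autosomes (SD, n = 80 windows). The incomplete last window of each chromosome was left out, here and in the bootstrap. The last of 10 equal parts, which includes that end, held 17.5 peaks per Mb on X and 44.2 on the autosomes. All 17 windows of X lay below the autosomal median of 50.5, as did 18 of 20 windows of V and 10 of 17 of IV, 7 of 15 of II, 3 of 13 of III and 2 of 15 of I. The fullest window of X, its first Mb, held 27 peaks, and 74 of the 80 autosomal windows held more, including 16 of 20 on V. The emptiest windows of X, from 8000001 to 10000000, held 8 peaks each. The densest autosomal windows held 90 peaks, on I from 9000001 to 10000000 and on III from 8000001 to 9000000. A bootstrap over windows gave a ratio of 0.265 (95% interval 0.220 to 0.319). With the chromosome as the unit, 1 X against 5 autosomes cannot give an exact permutation p under 0.167. Counted per protein-coding gene, the ratio of X to autosomes was 0.372 (0.326 to 0.422). The autosomes differed widely in this measure, from 154 peaks per 1000 protein-coding genes on V to 353 on I, against 92.3 on X.

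**Figure D1:**
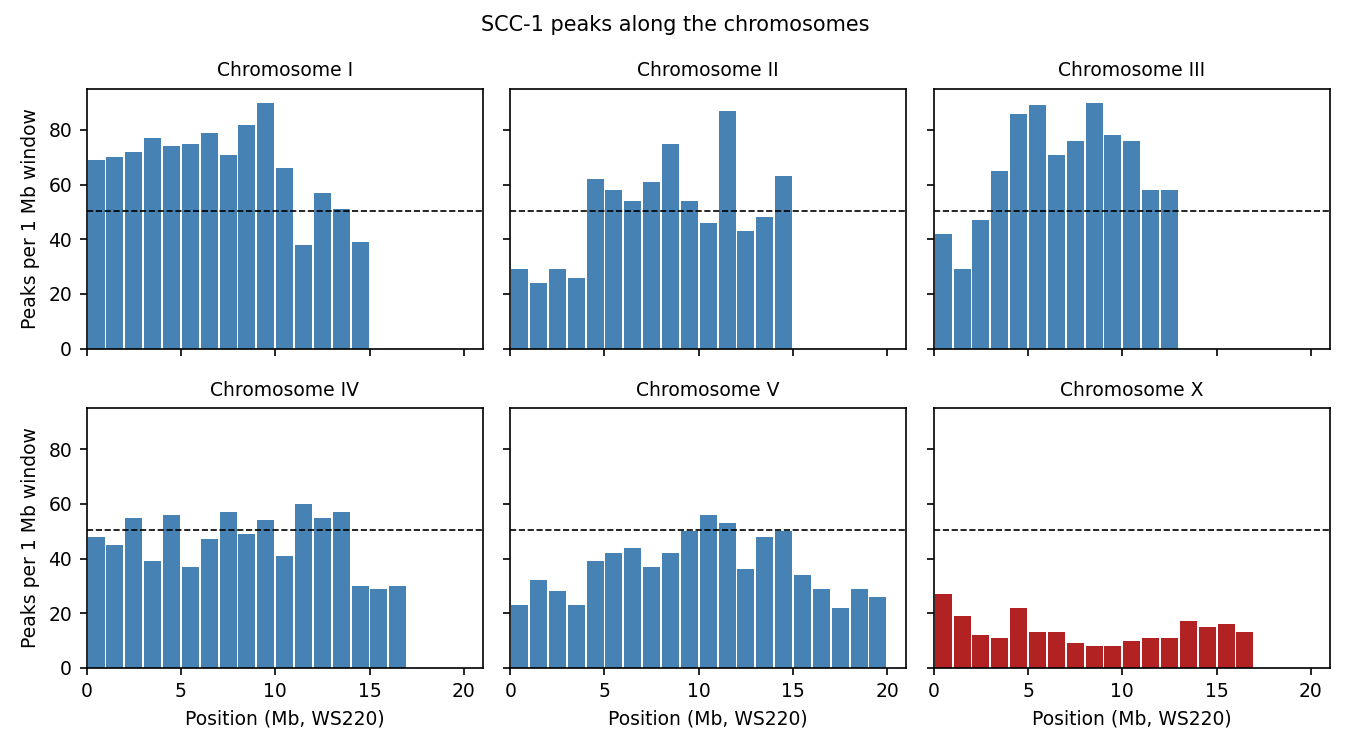
Number of SCC-1 peaks (vertical axis) in consecutive 1 Mb windows (horizontal axis, position in Mb in WS220) of each chromosome, with autosomes in blue and X in red; the dashed line is the autosomal median of 50.5 peaks, and incomplete last windows are left out. The 17 windows of X hold 8 to 27 peaks each, and the 20 windows of V, the sparsest autosome, hold 22 to 56.

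Peaks on X were narrower than autosomal peaks and had a lower median score, and X also held a set of peaks at the top of the score range. The median width was 1104 bp on X and 1515 bp on the autosomes (permutation p = 1e-05, the smallest that 100000 draws can give). The median score was 178 on X and 343 on the autosomes (permutation p = 0.003). Yet 31 of the 252 X peaks (12.302%, 95% interval 8.51 to 17.005) scored 3100 or more, against 426 of the 4282 autosomal peaks (9.95%, 9.07 to 10.9), a difference that did not pass Fisher's exact test (p = 0.236). Width and score are related in this list, so a comparison at like width also removes part of any difference in score. In the narrowest 2 of 5 classes of width, which held 170 of the 252 X peaks, the median score on X differed from that on the autosomes by 16.07 and -19.3. In the wider classes it was higher on X by 227, 2541 and 449, where the value of 2541 rests on 30 X peaks whose median was the ceiling of 3100. The average difference over X peaks was 374, and 81.6 without that class; neither was tested.

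Relative to the autosomes, X was poorest in peaks of intermediate score. The ratio of X to autosomal density was 0.392 (0.301 to 0.502) for scores from 50 up to 100 and 0.372 from 100 up to 250. It was 0.219 from 250 up to 500 and 0.111 (0.0618 to 0.185) from 500 up to 1000. From 1000 up to 3100 it was 0.165 (0.107 to 0.244), an interval that overlaps the one before. In the tied class of 3100 or more it was 0.338 (0.227 to 0.488). The ratio does not show where most peaks per Mb were missing. X held 4.46 per Mb against 11.98 from 100 up to 250, and 0.847 against 7.62 from 500 up to 1000. Of the peaks scoring at least 500, 31 of 72 on X (43.1%, 31.4 to 55.3) and 426 of 1786 on the autosomes (23.9%, 21.9 to 25.9) were in the top class. Fisher's exact test over peaks gave p = 4.29e-04. The division was chosen after seeing the data and follows the pattern, so this p-value is a description and no test of the pattern. Among the autosomes the top-class share ranged from 16.9% on III to 33.7% on IV, and the intervals of IV (28.8 to 38.9) and V (23.0 to 33.7) overlapped that of X. The top-class peaks of X had a median width of 2169 bp, against 3349 bp on the autosomes. Those on X included 6 in its first Mb, at 142295 to 144149, 160804 to 162520, 168206 to 170419, 329893 to 331793, 442440 to 444425 and 516035 to 517775.

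**Figure D2:**
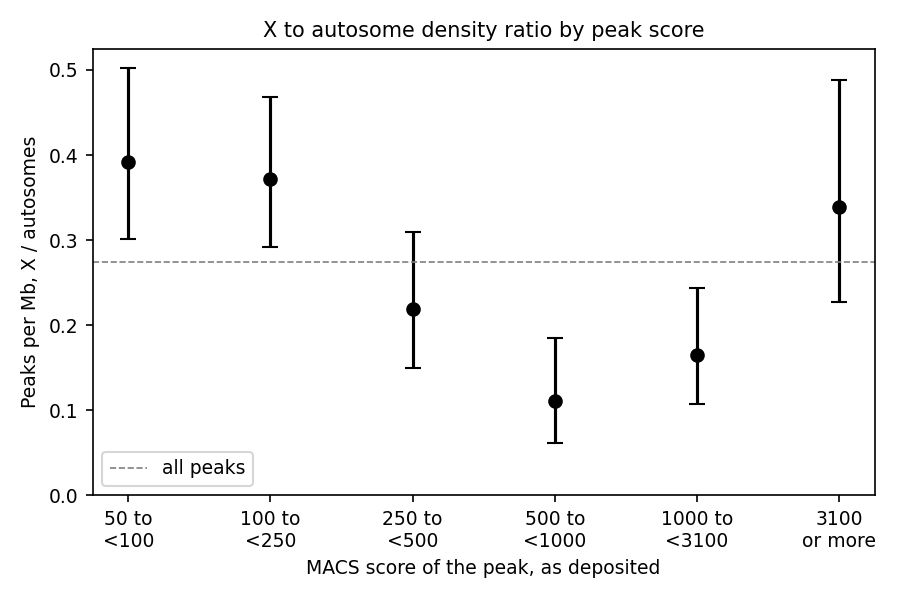
Ratio of peaks per Mb on X to peaks per Mb on the autosomes (vertical axis) for peaks grouped by their deposited MACS score (horizontal axis); points are ratios, bars are exact 95% intervals that cover counting error only, and the dashed line is the ratio of 0.274 for all peaks. The ratio is lowest, 0.111, for scores from 500 up to 1000 and is 0.338 at scores of 3100 or more.

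Pooled over the 5 autosomes, peaks were denser in chromosome centres, whereas peaks on X were not. The arms of worm autosomes recombine more in meiosis than the centres. Of the autosomal peaks, 42.2% (95% interval 40.7 to 43.6) lay on the arms, which make up 50% of the length, and 6 of 10000 rotations gave a share as low. Each autosome had fewer than 50% of its peaks on the arms, from 37.9% on V and 40% on III to 42.003% on II, 44.5% on I and 45.8% on IV. Taken singly, only V lay below the central 95% of its rotations (38.02 to 61.98). On chromosome II, the 4 windows of the first 4 Mb held 24 to 29 peaks each, and the window that followed held 62.

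On X, 61.1% of the peaks (154 of 252, 54.8 to 67.2) lay on the arms. This share alone was within the range of rotations of X (38.1 to 61.9), of which 9.65% gave a share as high. The difference from the autosomes was 19.0 percentage points, and 2 of 10000 rotations gave one as large in either direction (Fisher's exact test over peaks, p = 6.02e-09). The density on X ran from 23.1 peaks per Mb in the first of 10 equal parts to 9.03 in the fifth and the seventh, and was 17.5 in the last. Over the autosomes it ran from 41.3 in the first part to 63.6 in the sixth and 44.2 in the last.

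**Figure D3:**
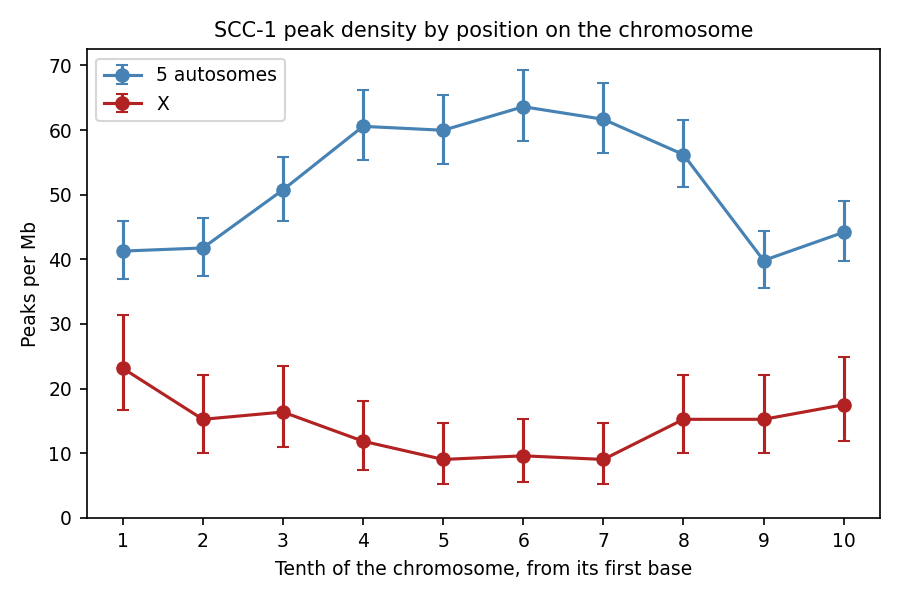
Peaks per Mb (vertical axis) in each of 10 equal parts of the chromosome counted from its first base (horizontal axis), for the 5 autosomes together in blue and X in red; bars are exact Poisson 95% intervals that cover counting error only. The autosomes are densest in the sixth part at 63.6 peaks per Mb, and X is densest in the first at 23.1.

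Autosomal peaks lay closer together than random placement gives. The median distance between the midpoints of neighbouring autosomal peaks was 8733 bp, against a median of 13450 bp over 1000 random placements, whose shortest value was 12841 bp. The placements gave every part of a chromosome the same expected density. Uneven density along a chromosome can also shorten the median, so the comparison does not separate it from local clustering. On X the median distance was 44603 bp against 49180 bp, and 72 of 1000 placements were as short, so no clustering was detectable there with 252 peaks. Over all chromosomes the ratio of the observed to the random distance was 0.653. It rose to 0.954 when peaks closer than 5000 bp were joined, with 4 of 1000 placements as short. For X alone it was then 1.07, with 875 of 1000 as short. The random placements of the joined peaks could still hold gaps under 5000 bp. These values therefore do not show how much clustering remains beyond that distance.

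Long stretches without a peak were found on every chromosome. The longest was on X, from 3651044 to 4137131 over 486 kb, followed on X by 7265679 to 7661268 over 396 kb. The median distance from the end of a peak to the next was 42795 bp on X and 5662 bp (III) to 9315 bp (V) on the autosomes. The lengths alone therefore do not show which stretch is unusual for its chromosome. The longest on the autosomes was on V, from 349711 to 723167 over 373 kb. The longest on the other autosomes were 250 kb on II from 3555966 to 3805688, 244 kb on I from 14113946 to 14357979, 226 kb on IV from 3816001 to 4041501 and 151 kb on III from 1626404 to 1777091. Reads that cannot be placed uniquely may also leave such stretches empty, depending on how they were handled. The list does not show which bases could be covered.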

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

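With 1 ChIP library and no read counts, no replicate could be left out and depth could not be varied. No planned or added alternative brought the X to autosome ratio (0.274) near 1. It was 0.203 in the higher-scoring 50% of the peaks, 0.206 as a share of bases covered and 0.372 per protein-coding gene. Added after seeing the data, it was 0.196, 0.187, 0.229 and 0.338 for scores of at least 250, 500, 1000 and 3100, and 0.402 with peaks closer than 5000 bp merged, which by construction joins more peaks where they are dense. Omitting each autosome gave 0.249 (without V) to 0.293 (without I). The higher-scoring 50% held 2267 peaks over 5.79% of the length. With arms as the outer 2 of 3 equal parts (66.7% of the length), 61.2% of all, 60.3% of autosomal and 76.2% of X peaks lay on them, the same directions as with 4 parts. Without the outer 1 Mb at each end the shares were 35.2% on the autosomes (43.1% of the bases left) and 51.96% on X (43.6% of the bases left). The clustering ratio of 0.653 became 0.954 with merging under 5000 bp. By construction, that merging removes the shortest distances from the list but not from the random placements. The lower median score of X (difference -166) became 512 higher in the higher-scoring 50%, a set chosen by the score itself, so this is no evidence that the direction turned. Within 5 classes of peak width, averaged over the X peaks, it was 374 higher, and 81.6 without 1 class of 30 X peaks whose median is the ceiling; the cause was not tested. Merging under 200 bp changed no direction. The alternatives that needed gene starts, exons or sequence were not run.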

Other observations

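Each chromosome began with a peak. The first peak started at base 1 on I, V and X and at base 2 on II, III and IV. These peaks were 1437 bp wide on I, 883 bp on II, 634 bp on III, 661 bp on IV, 764 bp on V and 733 bp on X, with scores of 818, 50.8, 331, 309, 610 and 906. Those on II, III, IV, V and X were at or below percentile 1.46 of all peak widths, and that on I was at percentile 47.2. A peak at the first bases cannot extend further out, so these widths are not comparable with those of other peaks. Whether these first peaks reflect SCC-1 binding was not tested. On II, III, IV and X the next peak began more than 40 kb further in, at 42881, 61794, 84130 and 42252. The other ends of the chromosomes were not analysed here because no chromosome length of the build was used.

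The tests of the lower signal on X and of the scores of neighbouring peaks were chosen only after the result was seen. The other tests of this part were written down before their values were computed. Of these, the merging under 5000 bp, the removal of chromosome ends and the rotations were still added after seeing the data.

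The shortage of peaks on X (ratio 0.274) was set against 3 explanations. The number of genes is a property of the chromosome, and the listing of domains as several peaks is technical. A lower signal on X may be technical or biological, which the list cannot tell apart. Fewer protein-coding genes on X, as the only cause, would bring the ratio per gene to 1, and it was 0.372 (0.326 to 0.422). Autosomal domains listed as several peaks each, as the only cause and with gaps under 5000 bp, would bring the ratio of merged peaks to 1. It was 0.402 (0.347 to 0.463). Neither value excludes that gene number or split domains account for part of the shortage. A single lower signal everywhere on X, which would leave peaks under the calling threshold, stays open: the ratio was 0.338 (0.227 to 0.488) at scores of 3100 or more and 0.140 (0.100 to 0.191) from 500 up to 3100, but the top class is saturated and decides nothing. A difference in the reads that could be placed on X, the use of the input as a control and a biological difference between X and autosomes, such as germline silencing of X, also stay open and were not tested, since the list holds no reads or expression values.

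The larger share of peaks on the arms of X than on those of the autosomes was not limited to the outermost 1 Mb at each end, without which 51.96% of X peaks (44.9 to 59.0) lay on arms that made up 43.6% of the bases left, a margin that is small and counts each peak as independent. Of the rotations, which keep the clustering of the peaks, 0.02% gave a difference as large. This argues against a chance arrangement on both X and the autosomes as the source of the difference. For the autosomes alone, 0.06% of the rotations gave a share as low. For X alone, 9.65% gave a share as high, so a chance arrangement of the X peaks is not excluded. Whether the pattern follows recombination, gene content or repeats was not tested.

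X holds 45.1% of the 612 tRNA genes and 5.56% of the peaks; no peak was assigned to a tRNA gene. The scores of neighbouring peaks had a Spearman's rho of 0.0412, which 4 of 1000 shuffles within chromosomes reached; this criterion was set after the value was seen, so it is a description and not a test of whether strong peaks neighbour strong peaks.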
